A study of Mus musculus with 8 samples.

How the data were processed

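RNA was measured by sequencing in 8 libraries of cells sorted by flow cytometry from pancreatic islets of adult mice. Per the labels, the animals carried a red nuclear reporter driven by the Ins1 promoter, which marks cells with an active insulin gene, and a yellow fluorescent protein switched on by a Cre recombinase expressed from the glucagon gene, which marks cells of alpha cell descent. Beta cells carried the red reporter (3 libraries), alpha cells the yellow label (3 libraries), and the cells called transdifferentiated carried both (2 libraries). Islets of several animals were pooled by sex for each library, which gave 4 male and 4 female pools. The replicates were taken to be separate samples. The titles of some libraries share a number with or without an added letter b, whose meaning is not given in the sources used here, so that p-values may in part measure technical spread. Beta replicates 2 and 3 and alpha replicates 2 and 3 carry the letter, and both transdifferentiated libraries, beta replicate 1 and alpha replicate 1 do not. The chi-square per degree of freedom between recovered read counts of 2 libraries of a group was 4 in the shallow transdifferentiated pair and 12.3 to 37.7 in the other pairs, so no pair differed by counting noise alone. Pairs that share a title number were beta replicates 1 and 2 (35.2) and alpha replicates 1 and 2 (34.4). Separate preparations of 1 pool would also differ by more than counting noise, so whether these are 1 pool was not settled.

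The deposited table holds RPKM (reads scaled by gene length in kilobases and by library size) for each gene and library, made by the authors. Per the submitters' processing notes, STAR 2.5, featureCounts, edgeR 3.14.0 and the mouse build GRCm38.p4 were used. The gene annotation, the strand setting and the exact library size behind the RPKM are not given in the sources used here. Per the labels' protocols, libraries were made with Illumina's TruSeq RNA kit v2, which does not mark strand, so reads of overlapping genes on opposite strands could not be told apart. Close relatives such as Ins1 and Ins2, or the trypsin and chymotrypsin families, can also share reads. Of 46959 entries, 27 carried names that a spreadsheet had turned into dates and were kept under those names, and 4 entries with repeated names were left out. There were 26786 genes above 0 in at least 1 library, and 20169 were at 0 in all of them. All columns of the table were used.

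Depth was recovered from the steps in the RPKM values. With exon lengths from GENCODE release M21, 78.5% of the expressed genes matched by symbol (19935 of 25394) came out as whole reads in all 8 libraries, within 0.01 of a read. The length of a further 6850 genes was solved from their own steps, which gave reads for 26785 genes. Recovered reads summed to 1469992 and 2573693 in the transdifferentiated libraries, 22466837, 25559011 and 17321677 in the beta libraries, and 14419204, 15004345 and 15721208 in the alpha libraries. The library size implied by the steps was below these sums. It was 0.847 and 0.842 times the sum in the transdifferentiated libraries, 0.828 to 0.837 in the beta and 0.895 to 0.897 in the alpha libraries. The deposited scaling thus differed between cell groups from one by recovered reads, for a reason not settled here. At a gene length of 2 kb, 1 read was worth 0.402 and 0.231 RPKM in the transdifferentiated libraries and 0.023 to 0.039 RPKM in the others. Low values of the transdifferentiated cells therefore rested on few reads.

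The main test was limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3 on log2(RPKM + 0.5), over 13172 genes with an RPKM of at least 1 in at least 2 of the 8 libraries. A single fit of all libraries with cell group and sex as terms gave the contrasts between cell groups and between sexes. A second fit on group-by-sex means tested whether the difference between alpha and beta cells differed between sexes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(RPKM + 0.5) scale, which understates changes of low genes, and are given with standard errors (SE). Means are given with the standard deviation (SD) over libraries. A gene lay outside the alpha to beta range when it was called in the same direction against both references. There were 25 gene lists, written from general knowledge, tested with camera at its preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison.

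The position of the transdifferentiated cells between the references was measured on linear RPKM as a share. For alpha-enriched genes the share was the value minus the beta mean, divided by the alpha mean minus the beta mean, and conversely for beta-enriched genes. These genes had an alpha to beta adjusted p under 0.05, an absolute log2 fold change of at least 3 and at least 10 RPKM in the higher group, so that the transdifferentiated libraries had a part in the choice only through the common fit. Intervals for the median share came from 2000 bootstrap draws over genes and leave out the spread between animals.

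Groups, tests, gene lists and most alternatives were fixed before the data were examined. The genes named were 18 islet genes; the 6 largest changes in each direction among called genes with at least 10 RPKM in the higher group and no overlap between groups; the 6 strongest genes outside the range in each direction; and up to 4 members of each list with the largest changes and at least 10 RPKM in the higher group. Genes outside the range needed at least 10 RPKM in the highest group, and between sexes up to 6 called genes in each direction were named. The alternatives were pseudocounts of 0.1 and 1, no filter or a filter of 5 RPKM, median-ratio scaling, quantile normalization, no trend, no sex term, only the groups compared, and leaving out each library in turn. Added after seeing the data were limma voom on the recovered reads, which weights values by depth, reads thinned at random to the 1469992 of the shallowest library, a filter on a mean of 10 RPKM, a term for the letter b in the titles, blocks of sex and that letter, shares on values scaled by the recovered reads, and shares against the reference libraries without the letter b.

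The procedure was tested on simulated reads drawn at the real depths with 67, 67 and 66 genes changed by folds of 2, 4 and 8. Between transdifferentiated and beta libraries it recovered 73.1%, 94% and 100% of them, and voom 64.2%, 74.6% and 97%, but 66 calls were false, 27% of all calls in this simulation. Between transdifferentiated and alpha libraries 92 calls were false, 33% of all calls. With so few changed genes these percentages are not those of the real calls. These false calls lay at low expression: among genes with a mean of at least 10 RPKM they were 2.1% and 7.7% of calls, and with voom 3.1% and 2.7% overall. Between alpha and beta libraries 4.7% of calls were false, and between sexes 2.6%. A simulated mix with 30% alpha RNA gave alpha shares of 27.7% and 30.2%. Coordinates are those of GENCODE M21 on GRCm38. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots. Some of the genes that the rule named are not reported here.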

Results

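The libraries compared 3 populations of mouse islet cells: alpha cells, which make glucagon, beta cells, which make insulin, and cells that carried the lineage mark of alpha cells while their insulin reporter was active. Expression was measured as RPKM in 3, 3 and 2 libraries. The transdifferentiated libraries were the shallowest, with 1469992 and 2573693 recovered reads against 14419204 to 25559011 in the others. The first principal component of log2 expression held 57.8% of the variance and placed the transdifferentiated libraries (scores of -15.7 and -17.4) between the beta libraries (-55.0 to -41.8) and the alpha libraries (56.4 to 63.4). The second component (15.9%) set them apart from all reference libraries and from each other, at 58 and 20.03 against -25.3 to -3.37. Pearson correlations across genes, which are not independent replicates, were 0.906 to 0.931 between transdifferentiated and beta libraries and 0.862 to 0.883 between transdifferentiated and alpha libraries. The transdifferentiated pair correlated at 0.914, below the 0.973 to 0.980 among beta libraries and 0.962 to 0.977 among alpha libraries. Lower depth can itself lower such correlations and shift the second component, and neither was computed at matched depth.

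The comparison of alpha with beta cells set the scale for the third population. Alpha cells held Gcg, the glucagon gene (chromosome 2, 62474530 to 62483650), at 180000 ± 14700 RPKM (SD, n = 3) against 959 ± 709 RPKM in beta cells (SD, n = 3), a log2 fold change of 7.84 (SE 0.49, adjusted p = 3.71e-05). Ins2, the major insulin gene of the mouse (chromosome 7, 142678656 to 142743381), was at 985 ± 145 RPKM in alpha cells against 138000 ± 20900 RPKM in beta cells (log2 fold change -7.20, SE 0.25, adjusted p = 3.51e-06). Of the 24 tested genes of beta identity, 22 were lower in alpha cells and 1 was higher, the zinc transporter gene Slc30a8 (log2 fold change 1.12). Of the 19 genes of alpha identity, 18 were higher (19 when adjusted over the list alone), among them the transcription factor genes Irx1 (5.85) and Irx2 (5.29). These lists passed camera with its preset correlation (adjusted p = 1.34e-15 and 1.39e-15), but not with the estimated one (adjusted p = 0.0774 and 0.135 with an estimated correlation).

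Other groups also separated the references. Of 24 genes of the unfolded protein response, which supports protein folding in the endoplasmic reticulum, 22 were lower in alpha cells (23 when adjusted over the list alone), led by Trib3 (log2 fold change -4.75), Chac1 (-4.14) and Ddit3 (-2.54); the list passed camera with its preset correlation (adjusted p = 8.62e-09) and not otherwise (adjusted p = 0.326 with an estimated correlation). Of 24 genes of oxidative phosphorylation, 10 were lower in alpha cells, including Cox5a (-1.12) and Ndufb8 (-0.73), both of the respiratory chain; adjusted over the list alone the number was also 10 (adjusted p = 0.0206, and adjusted p = 0.613 with an estimated correlation). Ppy and Pyy, hormone genes of PP cells, were higher in alpha cells by 3.18 and 4.0, and Ghrl made 3 of 3 in that list (adjusted p = 0.0159, and adjusted p = 0.525 with an estimated correlation). All 10 immune markers were lower in alpha than in beta cells, such as Cd74 (-4.11) and H2-Aa (-3.36), which act in antigen presentation (adjusted p = 5.09e-05, and adjusted p = 0.261 with an estimated correlation).

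In total 5743 genes differed between alpha and beta cells, 2229 higher and 3514 lower in alpha cells. The split of 38.8% higher became 53.1% with median-ratio scaling and 50% with quantile normalization, and the median log2 fold change over all genes moved from -0.05 to 0.07 and 0.02. Without alpha replicate 3 the count was 3117, and without beta replicate 3 it was 3430.

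The comparison of transdifferentiated with beta cells asked how far these cells had reached the beta cell transcriptome. Ins2 was at 90700 ± 5000 RPKM (SD, n = 2), 65.5% of the beta mean, a difference that did not pass the test (log2 fold change -0.64, SE 0.27, adjusted p = 0.154, and adjusted p = 0.04 with limma voom, the lowest of 22 alternatives). Transcription factor genes of beta cells that did not pass were Pdx1 at 66.2 ± 2.27 against 78.2 ± 4.81 RPKM (adjusted p = 0.429) and Nkx6-1 at 69.0 ± 6.63 against 91.9 ± 10.2 RPKM (adjusted p = 0.0626). Mafa, a transcription factor gene of mature beta cells (chromosome 15, 75745490 to 75748228), fell to 46.0 ± 5.05 RPKM, 34.8% of the beta mean of 132 ± 32.8 RPKM (log2 fold change -1.47, SE 0.20, adjusted p = 0.00981).

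Genes of beta cell identity and maturity fell as a group. Of 24 identity genes 10 fell and 14 did not pass the test (2 higher and 13 lower when adjusted over the list alone; adjusted p = 1.26e-07, and adjusted p = 0.105 with an estimated correlation). Of 15 maturity genes 8 fell and 7 did not pass (1 higher and 11 lower when adjusted over the list alone; adjusted p = 1.09e-06, and adjusted p = 0.105 with an estimated correlation). Examples were G6pc2, which encodes an islet glucose-6-phosphatase subunit (log2 fold change -1.08, SE 0.13, adjusted p = 0.0057), Sytl4, which encodes the granule protein granuphilin (-1.18, SE 0.13, adjusted p = 0.0044), the glucose transporter gene Slc2a2 (-1.17, SE 0.24, adjusted p = 0.0285) and Ucn3, a peptide hormone gene of mature beta cells (-0.68, SE 0.13, adjusted p = 0.023). Slc2a2 and Ucn3 missed the threshold in 8 and 6 of 22 alternatives. Ins1 (-0.77, SE 0.19, adjusted p = 0.0461) missed it in 14 of 22, with adjusted p up to 0.698.

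Genes of alpha identity were higher than in beta cells: 16 of 19 rose and 3 did not pass (17 higher when adjusted over the list alone; adjusted p = 1.83e-11, and adjusted p = 0.161 with an estimated correlation). Gcg was at 19200 ± 191 RPKM (SD, n = 2), with a log2 fold change of 4.60 (SE 0.53, adjusted p = 0.00538, and adjusted p = 0.349 without a filter on low values). Irx2 rose by 3.73 (SE 0.19, adjusted p = 0.000844) and Ttr, the transthyretin gene, by 2.57 (SE 0.19, adjusted p = 0.00163). The largest rises also included Eef1a2, an isoform of a translation elongation factor (3.91), and Pdk4, a kinase that inhibits pyruvate dehydrogenase (3.73). Both were also higher in alpha than in beta cells.

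Hormone genes of other islet cells were raised against beta cells. Pyy rose by 3.88 (adjusted p = 0.00303), Ppy by 3.32 (adjusted p = 0.00538) and Sst, the somatostatin gene of delta cells, by 2.58 (adjusted p = 0.0273, missing the threshold in 8 of 22 alternatives). Of 9 delta cell markers 6 rose (8 when adjusted over the list alone; adjusted p = 0.000447, and adjusted p = 0.376 with an estimated correlation), and 2 of 3 PP and epsilon cell markers rose, with the same count adjusted over the list alone (adjusted p = 0.0185, and adjusted p = 0.438 with an estimated correlation). Of 14 genes linked to beta cell immaturity 6 rose, likewise 6 adjusted over the list alone, including Rbp4 (2.97) and Cd81 (1.20). That list passed camera (adjusted p = 0.0186, and adjusted p = 0.376 with an estimated correlation), and some of its members, such as Pyy and Rbp4, are also on the lists of PP or delta cell markers. Limma voom called 3 genes in each of the delta cell and immaturity lists, and with the letter b of the titles as a term 3 delta cell markers were higher and 1 was lower. With that term 2 PP and epsilon cell markers were still higher, but their list did not pass camera (adjusted p = 0.11).

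Of 24 unfolded protein response genes 2 fell, Edem1 (-1.03) and Dnajb11 (-0.47), and 22 did not pass (4 lower when adjusted over the list alone; adjusted p = 5.58e-07, and adjusted p = 0.376 with an estimated correlation). Limma voom called 1 of them, and 7 fell with the letter b as a term. No gene of oxidative phosphorylation was called by limma among 24 tested or adjusted over the list alone (5 had an unadjusted p under 0.05, and limma voom called 0), although the list as a whole passed camera toward lower values (median log2 fold change -0.10, adjusted p = 0.0127, and adjusted p = 0.614 with an estimated correlation). Of 18 receptor genes 7 rose and 3 fell (8 and 4 when adjusted over the list alone), among them Ffar4, a fatty acid receptor gene (2.01), Gpr119 (1.54) and the glucagon receptor gene Gcgr (-1.01). Limma voom called 5 of the 18, and the list did not pass camera (adjusted p = 0.649). Of 22 genes of stimulus-secretion coupling 3 rose and 2 fell, with the same numbers adjusted over the list alone; Abcc8, a subunit of the ATP-sensitive potassium channel, rose by 0.63 (adjusted p = 0.0189).

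Immune markers stood out among the genes that fell against beta cells. Of 10 tested, 8 fell (10 when adjusted over the list alone; adjusted p = 5.62e-10, and adjusted p = 0.105 with an estimated correlation). Limma voom called only 2 of the 10. These markers were also lower in alpha than in beta cells, so the beta libraries were the high group. Their mean log2 values were 2.94 to 3.2 in beta, 1.53 and 0.86 in transdifferentiated and 0.46 to 0.75 in alpha libraries. Carry-over of immune cells into the beta sort was not tested. Cd74 was at 7.29 ± 6.61 RPKM against 35.4 ± 3.70 RPKM in beta cells (log2 fold change -2.62, adjusted p = 0.0142), and H2-Aa at 2.27 ± 0.427 against 10.1 ± 0.416 RPKM (-1.94, adjusted p = 0.00316). Ctss, the cathepsin S gene (-3.36), and H2-Eb1 (-2.54) were also among the 6 largest falls, together with Msln (-3.01), Emilin1 (-2.57) and Gad1, which encodes a glutamate decarboxylase (-2.49).

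In all, 1580 genes differed from beta cells, 1198 higher and 382 lower. Of the 1198 higher genes, 763 (63.7%) were higher in alpha than in beta cells. Of the 382 lower genes, 300 (78.5%) were higher in beta than in alpha cells. Over all 13172 genes tested these classes made up 16.9% and 26.7%, and independent lists would share 202.7 and 101.9 genes. Both comparisons use the same 3 beta libraries, which cannot be split into parts of 2. In simulated reads without any difference, lists of the same lengths ranked by p shared 426 to 488 higher and 173 to 208 lower genes. Such lists hold noise alone. At the threshold itself these simulations called 0 to 6 genes higher than in beta cells, 0 of them higher in alpha cells. They called 2 to 41 lower, 0 to 1 of them lower in alpha cells. Part of the overlap may come from the shared libraries, but how much was not settled. The split of 75.8% higher became 59.8% with median-ratio scaling and 55.2% with quantile normalization, and the median log2 fold change over all genes moved from 0.09 to 0.01 and -0.04. Limma voom on the recovered reads called 569 genes, and 485 were called among genes with a mean of at least 10 RPKM. The count also varied when libraries were left out: 508, 805 and 235 without beta replicates 1, 2 and 3. It was 861 and 974 without alpha replicates 2 and 3, which are not part of this contrast. Leaving out a library also lowers the power of the test, so these counts do not show that the differences rested on single libraries.

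**Figure D1:**
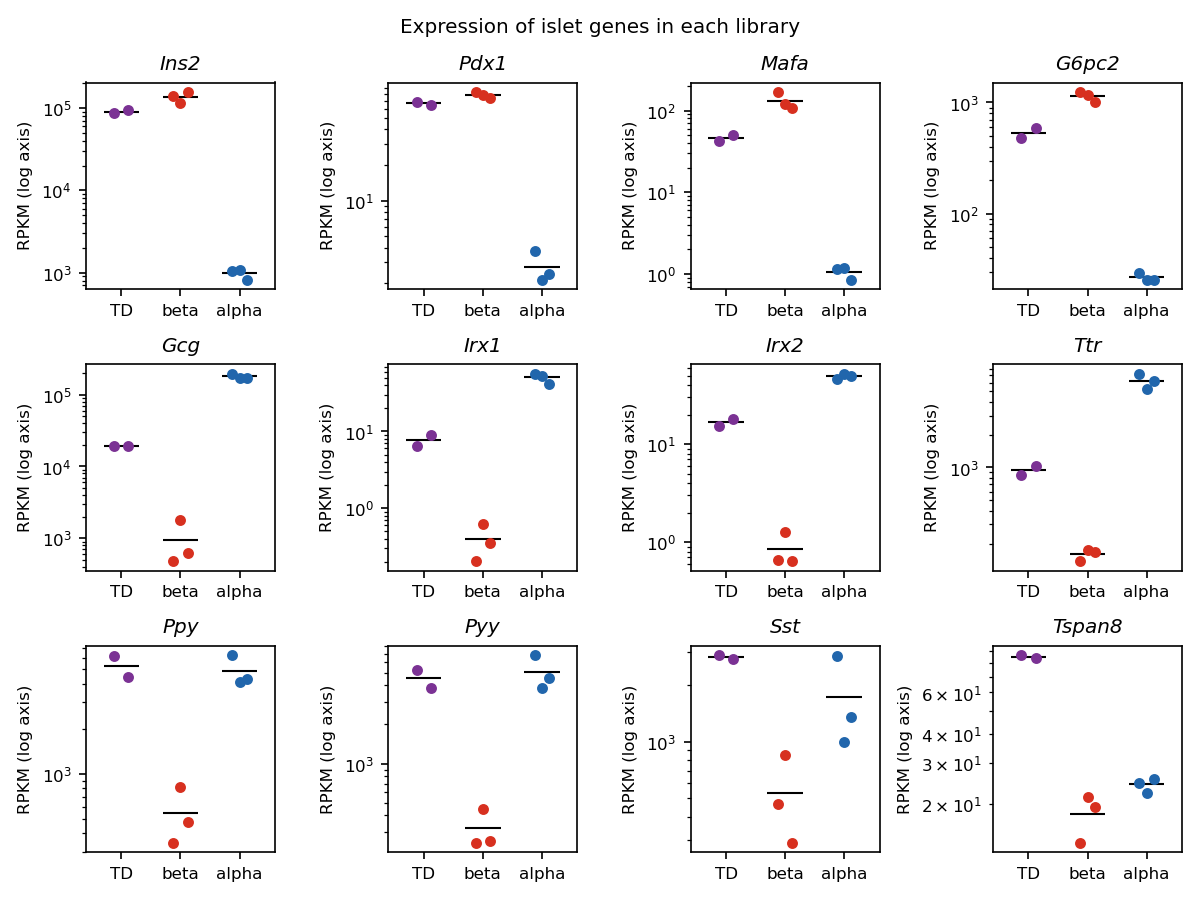
RPKM of 12 islet genes in each library on log axes (TD, transdifferentiated cells, 2 libraries; beta and alpha cells, 3 libraries each); every point is a library and the black line is the group mean. Ins2 and Pdx1 of the transdifferentiated cells lay closer to the beta than to the alpha level (means of 90700 and 66.2 RPKM), Gcg (mean 19200 RPKM), Irx1, Irx2 and Ttr between both references, and Tspan8 (mean 85.3 RPKM) above both.

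The comparison with alpha cells asked how far the same cells had left the alpha cell transcriptome. Transdifferentiated cells held Gcg at 10.7% of the alpha mean (log2 fold change -3.25, SE 0.53, adjusted p = 0.00453, and adjusted p = 0.44 without a filter on low values). Ttr was at 15.1% (-2.73, SE 0.19, adjusted p = 0.00014) and Irx2 at 34.1% of the alpha mean (-1.56, SE 0.19, adjusted p = 0.00149). Of 19 alpha identity genes 17 fell, Tspan8 rose (1.80) and 1 did not pass, with the same numbers adjusted over the list alone (adjusted p = 1.67e-16, and adjusted p = 0.122 with an estimated correlation). Of 24 beta identity genes 23 rose and 1 fell, also adjusted over the list alone (adjusted p = 9.71e-18, and adjusted p = 0.0608 with an estimated correlation). Examples were Ins2 (log2 fold change 6.57, adjusted p = 1.83e-05), Ucn3 (5.98) and Glp1r, the GLP-1 receptor gene (5.21); the gene that fell was Slc30a8 (-0.71).

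Maturity genes followed the beta side, with 12 of 15 higher than in alpha cells and 1 lower, and the same numbers adjusted over the list alone (adjusted p = 3.55e-08, and adjusted p = 0.0673 with an estimated correlation). Of 24 unfolded protein response genes 18 rose (19 adjusted over the list alone; adjusted p = 3.28e-06, and adjusted p = 0.663 with an estimated correlation), led by Trib3 (3.82), Chac1 (3.60), Ddit3 (2.17) and Asns (1.94), genes induced when cells lack amino acids or hold unfolded proteins. Of 9 genes normally silent in beta cells 3 fell and 2 rose, likewise adjusted over the list alone; the list passed camera toward lower values (adjusted p = 0.0281, and adjusted p = 0.692 with an estimated correlation), and Oat, the ornithine aminotransferase gene, fell by 2.38 on the log2 scale. The PP hormone genes did not pass against alpha cells: Pyy was at 4560 ± 1030 against 5060 ± 1550 RPKM (adjusted p = 0.837) and Ppy at 5290 ± 1230 against 4890 ± 1150 RPKM (adjusted p = 0.814). Sst was at 2820 ± 96.8 against 1730 ± 978 RPKM (adjusted p = 0.299).

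Against alpha cells 3932 genes were called, 3053 higher and 879 lower. The split of 77.6% higher became 52.5% with median-ratio scaling and 49.9% with quantile normalization, and the median log2 fold change over all genes moved from 0.17 to -0.03 and -0.05. Limma voom called 2236 genes, and without alpha replicate 3 the count was 2447.

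The share of each reference in the transdifferentiated cells was read on genes that separate alpha from beta cells most. Over 76 alpha-enriched genes the median share of the alpha level was 16.2% in replicate 1 (bootstrap interval over genes 12.8% to 18.5%) and 17.3% in replicate 2 (14.4% to 23.4%). Over 98 beta-enriched genes the median share of the beta level was 57.0% (52.0% to 63.9%) and 61.1% (53.3% to 68.1%). Shares differed widely between genes: the 10th and 90th percentiles of the beta share were 25.1% and 101% in replicate 1 and 31% and 89.7% in replicate 2. The beta-enriched genes included Cd74, H2-Aa, H2-Eb1 and Ctss, with shares of -0.9% to 30%. With genes chosen at a fold of at least 2, the mean of both replicates rose from 16.8% to 29.2% for the alpha share and from 59.1% to 65.8% for the beta share. On the log2 scale these means were 50.9% and 84.9%.

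**Figure D2:**
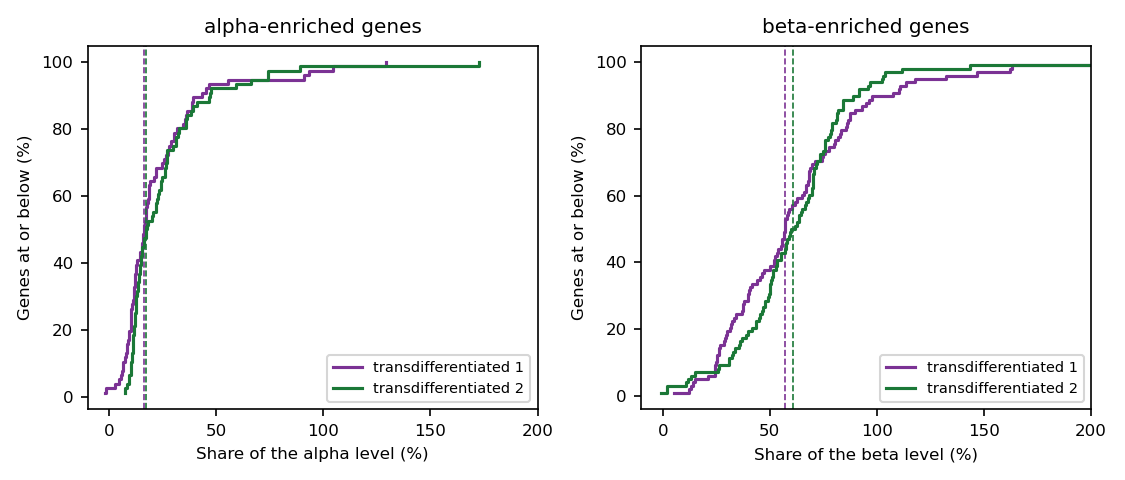
Cumulative distributions over genes of the share of the alpha level (left, 76 genes) and of the beta level (right, 98 genes) in the transdifferentiated libraries, in percent on both axes; dashed lines mark the medians. The curves of both libraries lay close together, with medians of 16.2% and 17.3% on the left and 57.0% and 61.1% on the right; Mlxipl lay beyond the right end of the beta axis in each library.

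Some genes lay outside the range between the references. The clearest was Tspan8, which encodes a membrane protein of the tetraspanin family and is on the lists of alpha identity and of duct markers (chromosome 10, 115816832 to 115849893), at 85.3 ± 1.86 RPKM against 18.2 ± 4.03 in beta and 24.3 ± 1.67 in alpha cells (log2 fold changes 2.22 and 1.80, adjusted p = 0.0025 and 0.000665). It was called against both in all 22 alternatives. Plekhg6 was at 16.5 ± 9.07 RPKM against 2.5 ± 0.243 and 2.12 ± 0.346 (adjusted p = 0.00879 and 0.00128), and Apof, an apolipoprotein gene, at 12.5 ± 2.87 against 2.44 ± 0.628 and 3.06 ± 0.543 (adjusted p = 0.0044 and 0.00128). The small RNA genes Snord71, Snord55 and Gm22771 were named by the same rule but rested on 1 to 3 reads in each transdifferentiated library. Among genes with at least 10 RPKM in the highest group, the strongest below both references were Psmg2, Haus7, Tomm5, Maob, Rpl15 and Scd2, of which Psmg2, a proteasome assembly factor gene, had log2 fold changes of -1.15 and -0.61; with limma voom none of the 6 passed against both.

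In total 388 genes lay outside the range, 315 above and 73 below, 8.2% of the 4733 genes called against either reference. Many of them rested on few reads. Below both references, genes such as mt-Tn, Snord32a and Cox7a1 had 0 reads in each transdifferentiated library. Above both, genes such as n-R5s73 and Gm12926 had 1 read in each. Median-ratio scaling gave 135 above and 114 below, quantile normalization 104 and 119, and limma voom 82, all above, of which 80 were shared. When a beta or alpha library was left out, voom put 10 to 92 genes outside. Both contrasts share the transdifferentiated libraries: independent lists of these sizes would overlap in 278 higher and 25.5 lower genes, and in simulated reads without any difference lists of the same lengths ranked by p shared 961 to 1008 and 280 to 322. At the threshold itself these simulations put 2 to 31 genes outside (median 18.5). A split into parts with 2 transdifferentiated libraries each was not possible. Lists of fixed length from reads without any difference are ranked by shared noise alone. They do not measure how much sharing adds to the real overlap, which stays open. In 50 simulated mixes of alpha and beta RNA at the real depths, 19 to 51 genes lay outside, 1 to 10 of them above. If transdifferentiated libraries vary like the references, sharing them does not account in full for the 315 genes above. The count was 201 and 591 without transdifferentiated replicates 1 and 2, 131, 163 and 43 without beta replicates 1, 2 and 3, and 235, 158 and 203 without alpha replicates 1, 2 and 3.

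Pools of male and female animals differed in 6 genes. The Y-linked genes Eif2s3y (log2 fold change 4.99, SE 0.14, adjusted p = 3.31e-05), Ddx3y (4.87), Uty (3.32) and Kdm5d (2.74) and the predicted gene Gm29650 (3.18) were higher in males. Xist, the RNA that silences an X chromosome in female cells, was lower (-6.63, SE 0.63, adjusted p = 0.0272, missing the threshold in 10 of 21 alternatives). All 4 listed Y genes rose, also adjusted over the list alone (adjusted p = 5.44e-23, and adjusted p = 0.068 with an estimated correlation), and of 5 listed X-linked genes only Xist fell with adjustment over all genes (4 lower when adjusted over the list alone; adjusted p = 9.7e-11, and adjusted p = 0.0816 with an estimated correlation). The lists of unfolded protein response (adjusted p = 0.0335, and adjusted p = 0.847 with an estimated correlation) and oxidative phosphorylation (adjusted p = 0.00943, and adjusted p = 0.847 with an estimated correlation) passed camera with no member called by limma or limma voom (0 and 2 with an unadjusted p under 0.05). Without beta replicate 3, a male pool, 2 genes were called. The test of the alpha to beta difference by sex rested on a single male beta and a single female alpha library. It therefore had little power, and few calls do not show that the sexes were alike. For the difference between alpha and beta cells by sex, limma called 0 of 13172 genes; 201 had an unadjusted p under 0.05, and limma voom called 0 (119 unadjusted). Without a filter on low values 668 genes were called, of which 10 pass the filter.

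Markers of other cell types that a sort could carry over were compared in the same way. None of 19 acinar markers was called by limma or limma voom between any pair of cell groups, also adjusted over the list alone, and 0 had an unadjusted p under 0.05. They varied widely between libraries: Ctrb1, a chymotrypsinogen gene, was at 368 and 125 RPKM in the transdifferentiated libraries, 50.8, 1460 and 683 RPKM in the beta libraries and 17.0, 927 and 264 RPKM in the alpha libraries. Among the reference libraries these levels followed a letter b in the titles, which replicates 2 and 3 of beta and of alpha cells carry. The transdifferentiated libraries lack the letter, and the acinar mean of replicate 1 (a log2 value of 5.1) was above that of alpha replicate 3 (4.57), which carries it. With that letter as a term, 14 acinar markers were higher than in alpha cells and 0 were called against beta cells, and the list passed camera in both comparisons (median log2 fold changes 3.36 and 2.06, adjusted p = 0.000957 and 0.00908, and adjusted p = 0.636 and 0.804 with an estimated correlation). Of 9 duct markers 2 were higher in transdifferentiated than in beta cells and none lower, and against alpha cells 3 were higher and 1 lower (4 and 1 when adjusted over the list alone), but the list passed camera in neither (adjusted p = 0.764 and 0.533). Of 3 stromal markers 1 was higher than in beta cells and all 3, Tagln, Sparc and Vim, were higher than in alpha cells, with a median log2 fold change of 1.39 and the same counts adjusted over the list alone. Limma voom called 0 and 1 of them, and the list passed camera in neither comparison (adjusted p = 0.243 and 0.273). Of 2 endothelial markers 1 was higher than in beta cells and 0 were called against alpha cells. Of 3 Schwann cell markers limma and limma voom called 0 against either. No erythroid marker passed the filter on low values.

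Of the remaining lists, 1 of 20 genes of dissociation stress, 1 of 17 genes of glycolysis, 1 of 18 pan-endocrine genes and 2 of 9 genes normally silent in beta cells were higher in transdifferentiated than in beta cells, with the same counts adjusted over the list alone. The lists of proliferation (8 tested) and of antigen presentation and interferon (18 tested) held no called gene in that comparison, with limma or limma voom (0 and 1 with an unadjusted p under 0.05). With the letter b as a term, 9 of the 18 interferon genes were higher than in beta cells and 10 higher than in alpha cells (adjusted p = 9.01e-05 and 0.00123, and adjusted p = 0.599 and 0.636 with an estimated correlation). Without that term none of these lists passed camera against beta cells (adjusted p = 0.154 to 0.913).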

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

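The alternatives with limma voom, thinned reads, a mean of at least 10 RPKM, values scaled by the recovered reads and the letter b of the titles were chosen only after the results were seen. Counts not given here stayed within 1.5 times the reported one. The 1580 genes between transdifferentiated and beta cells became 877 without a filter, 283 with only the groups compared, 569 with limma voom, 150 with thinned reads and 485 at a mean of at least 10 RPKM, and 235 to 1649 when single libraries were left out. Against alpha cells, 3932 became 2366 with only the groups compared, 2236 with voom, 1692 with thinned reads and 2002 at a mean of at least 10 RPKM, and 2447 to 3735 without single libraries. Between alpha and beta cells, 5743 became 3462 with thinned reads and 2738 at a mean of at least 10 RPKM, and 3117 to 6609 without single libraries. Between sexes, 6 became 1 at a mean of at least 10 RPKM and 2 to 6 without single libraries. The test of the alpha to beta difference between sexes gave 668 genes without a filter and 0 in its other alternatives. The 388 genes outside the range became 248 without a filter, 231 with a filter of 5 RPKM, 249 with median-ratio scaling, 223 with quantile normalization, 82 with voom, 18 with thinned reads and 83 at a mean of at least 10 RPKM, and 43 to 591 without single libraries. Filters and thinning leave fewer genes or reads; the cause of the other changes was not tested.

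Of the gene lists, 9, 5, 8 and 4 passed in the comparisons with beta cells, with alpha cells, of alpha with beta cells and of sexes. With an estimated correlation 0 passed in each, and without single libraries 7 to 10, 4 to 6, 6 to 10 and 2 to 6. With the letter b as a term or in blocks with sex, 8 lists passed against alpha cells. The alpha share of 16.8% became 14.2% with median-ratio scaling, 29.2% at a fold of at least 2 and 50.9% on the log2 scale, and 16.1% to 17.7% without single libraries. The beta share of 59.1% became 54.0%, 65.8% and 84.9%, and 56.5% to 61.9%, and 53.1% against the references without the letter b. Ddx3x changed direction between alpha and beta cells with quantile normalization (a log2 fold change of 0.039 in place of -0.33, with adjusted p = 0.792 in place of 0.0388); the cause was not tested. Of 264 results for named genes, voom kept the call in 231, lost it in 31 and gained it in 2. Thinning kept 212 and lost 52, and leaving out beta replicate 3 kept 222 and lost 42. The term for the letter b kept 231, lost 10 and gained 23, and put 509 genes outside the range. Pairing by replicate number was not possible, because no replicate number ties libraries of different groups together. Sex and the letter b do tie them, in 4 blocks of 2 libraries, and with these blocks 1943 genes were called against beta cells, 3165 against alpha cells, 5605 between alpha and beta cells and 6 between sexes, with 509 outside the range. Of the named results 232 kept the call, 7 lost it and 25 gained it.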

Other observations

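The depth test, the readings of the genes outside the range with limma voom, without single libraries and in held-out libraries, the simulated mixes, the sums of shares other than the first pair, and the reading by the letter b of the titles were chosen only after the results were seen. The genes named in the next paragraph were also chosen after their values were seen.

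Among genes above both references was Mlxipl, which encodes a glucose-responsive transcription factor, at 85.6 and 55.1 RPKM in the transdifferentiated libraries against 13.4 to 26.7 RPKM in beta and 1.83 to 2.46 RPKM in alpha libraries. Neurog3, a transcription factor gene of endocrine progenitors, was at 2.61 and 3.0 RPKM (5 and 10 reads) against 0.174 to 0.589 RPKM in beta and 0.339 to 1.36 RPKM in alpha libraries. Ghsr, the ghrelin receptor gene, was at 3.08 and 2.19 RPKM (17 and 21 reads) against at most 0.601 RPKM in beta and 1.48 RPKM in alpha libraries. With limma voom Mlxipl passed against both references, and neither Neurog3 nor Ghsr did. Xist was at 6.05 RPKM (135 reads) in the male transdifferentiated library, against 0.158 to 0.255 RPKM in the other male libraries and 50.8 to 221 RPKM in the female ones. In the female transdifferentiated library the Y-linked gene Eif2s3y was at 0.333 RPKM (3 reads), against at most 0.0341 RPKM in the other female libraries. Uty and Kdm5d were at 0 there. The source of these Xist and Eif2s3y reads was not tested.

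Transdifferentiated libraries held transcripts of both alpha and beta cells, and a candidate explanation is a mix of both cell types, as from doublets. Such a mix gives shares that sum to 1 (0.966 to 1.02 in 50 simulated mixes). The simulated mixes were drawn from the reference means that the shares themselves use, so their range leaves out error in those means. The sums were 0.733 (0.676 to 0.809) and 0.784 (0.710 to 0.884), which argues against a mix of these profiles as the whole account at this choice of genes. Against the references without the letter b they were 0.698 (0.573 to 0.773) and 0.705 (0.639 to 0.809). At a fold of at least 2 they were 0.9 (0.854 to 0.957) and 1.0 (0.957 to 1.05), so that only the interval of replicate 2 held 1, and with median-ratio scaling at that fold 0.747 (0.699 to 0.794) and 0.879 (0.844 to 0.921). A mix in part of the cells, a mix with another cell type and the state of cells changing from alpha to beta, which the sort was made to collect, stay open, the last untested.

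Genes outside the range were 8.2% of those called against either reference. This is above the 5% set in advance as the most that a mix of alpha and beta cells may give. When a beta or alpha library was left out, 4 fits gave less than 5% (range 1.3% to 6.8%). Leaving out a library also lowers the power of the test, so this range does not measure the spread of the 8.2%. Whether the bound was passed beyond that spread was therefore not settled. The letter b as a term and blocks of sex and letter gave 11.6% and 12%. Limma voom gave 3.2%, thinned reads 1% and a mean of at least 10 RPKM 3.7%. Of genes with 10 RPKM or more that were at least 2 times both references in one transdifferentiated library, 50% to 75% were above both in the other library against reference libraries not used to pick them (30.8% to 64.3% with median-ratio scaling). Of all genes at that level 36% to 39.2% were above both (20% to 21.6% with median-ratio scaling). A mix allows up to 50% for genes whose noise exceeds the gap between the references. That is the most that a mix allows, not what it must give, so the 7 of 8 Wilson intervals that held 50% do not favour a mix. Each pick gave a higher percentage than all genes at that level, though some lower Wilson bounds, such as 29.9% against 39.2%, did not. For these genes as a set, this held-out test cannot tell a mix from another state. Tspan8, itself a listed duct marker, was at 86.6 and 84.0 RPKM against at most 25.7 RPKM in any reference library. It lay beyond any mix of these profiles. Of the 388 genes, 315 of them above, 80 stayed among the 82 outside with limma voom. When a beta or alpha library was left out, voom put 10 to 92 outside. Simulated reads at these depths put 2 to 31 outside with no effect. As a mix they put 19 to 51 outside, 1 to 10 of them above both references, and 0 to 1 outside with voom. If transdifferentiated libraries vary like the references, these counts argue against a mix of these profiles as the whole account of the genes above. Whether they vary so was not tested, and how many of the genes lower depth may account for stays open. RNA of other cell types could add to the genes above both: 4 of 315 were markers of such types, Sst was above the mean of both references in both libraries while the 18 acinar and 4 immune ones were not, yet the acinar mean (log2 values of 5.1 and 3.72) was above the 2.49 and 1.35 of the references without the letter b.

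Other splits of the libraries were tested for 3 counts. For alpha against beta cells the real split gave 5743 genes and the highest of the others 0, with 1 of 10 splits as large, too few for a share under 0.05. For the sexes, 3 of 35 splits gave at least the real 6 genes, so this count alone does not exclude chance. The 2 others, with 502 genes, put all beta and all alpha libraries on opposite sides. With cell group as a term such a split compares only transdifferentiated replicate 1 with replicate 2, not alpha with beta cells. All 4 listed Y genes were higher in every male than in every female library, such as Uty at 3.76 to 5.91 RPKM in male and at most 0.00725 RPKM in female ones. For the alpha to beta difference between sexes, 9 of 9 assignments gave at least the real 0 genes, which a count of 0 makes certain, so this test says nothing; the highest other gave 2.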
